A study of Homo sapiens with 34 samples.

How the data were processed

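Total RNA of hTERT RPE-1 cells was sequenced after ribosomal RNA depletion as stranded libraries, 34 in all, in 17 hgRNA groups of 2 biological duplicates. Per the labels, cells were transduced at less than 1 virus per cell, selected with puromycin at 20 µg/ml for 72 h, grown for 4 more days and harvested at 50 to 70% confluency. The labels name no batch, date or sequencing run, and over all groups replicate numbers did not pair the samples. Of 136 pairs of groups 28 had a correlation above 0.1 between their replicate differences, with a median of -0.00638. Among these were all 6 pairs of knockouts (0.369 to 0.497) and all 3 pairs of control, DDX17 deletion and HDAC7 deletion hgRNA 1 (0.518 to 0.663), so within these sets libraries of a replicate number went together. Columns of 2 further libraries, absent from the sample list, were not used.

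The authors used Salmon 1.10 and edgeR (version not given) for the deposited expression table; aligner, genome build and annotation are not given in the sources used here. That table holds, per the file headers, RPKM (reads scaled for transcript length and depth) with 1 column per hgRNA and a single control column, log2 fold changes against the controls, and p-values with their false discovery rates (FDR), all by the authors and all with replicates combined. A deposited splicing table gives a score from 0 to 1 per event and hgRNA, headed only as a significance. Another deposited table, by its header from vast-tools, holds the percent inclusion or retention per event and library with a quality string, from which counts of junction reads per library could be read. Spliced-junction counts were whole numbers (100%). The table lists 721536 events, of which 399179 had 10 reads or more in a control library and were kept. Intron positions matched GENCODE v29 on GRCh38 for 192907 of 192950 introns (99.98%), and that annotation was used for positions, gene types, GC content and length.

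No table of gene counts per library was among the files used, and the choices made before the data were examined had assumed counts or RPKM per library. Gene expression was therefore measured as reads across the spliced junctions of introns, summed per gene from 29324 genes with an intron event. Genes without introns, among them replication-dependent histones and mitochondrially encoded genes, have no such value, and for these the authors' deposited table was read instead. Libraries held 12353936 to 20233610 such reads. Genes needed a count of 10 at the median depth in 2 libraries and a total of 15, which left 12081. Counts were scaled by TMM factors computed in the scripts and tested with limma 3.58.1 (voom weights, moderated t) in R 4.3.3, with a coefficient per hgRNA group, 17 residual and 5.83 prior degrees of freedom. An edited comparison was the mean of its hgRNAs minus the mean of the 2 control hgRNAs. Genes past a Benjamini-Hochberg adjusted p of 0.05 were called. All adjusted p-values for genes, events and lists come from limma.

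Splicing events were tested as the log2 ratio of inclusion to exclusion reads with a pseudocount of 1 on each, for events with 20 reads in every library of a comparison, again with limma. An event was called past an adjusted p of 0.05 with a difference of 10 percentage points in mean. Events of the 5 edited genes were also adjusted alone. Tables were parsed with Python 3.11.15 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

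Genes were grouped by 27 lists written before the data were examined. They cover cell-cycle, p53, RNA-processing, stress, immune, matrix, metabolic, HDAC, ribosomal, histone and mitochondrial genes and markers of retinal pigment epithelium and of other cells. Lists were tested with camera in limma at an inter-gene correlation of 0.01 and again with the correlation estimated from the residuals. Counts of members past the threshold are given over all genes and with members adjusted over the list alone.

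Genes named in the text follow a rule, and some that it picks are not reported here. The 5 edited genes were tabulated in every comparison and are given where they were edited or called. Up to 8 higher and 8 lower genes per comparison were named, those with the largest log2 change among protein-coding genes and named long noncoding RNAs that passed the threshold, had the same sign in each hgRNA, a mean log2 CPM of at least 2, and every edited library beyond the range of the 4 controls. Up to 4 members with the smallest p were added for each list that was called or had at least 3 members past the threshold. Named events were every called event of an edited gene and up to 5 introns and 5 cassette exons with the largest differences, same in sign in each hgRNA and with every edited library beyond the controls.

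Guides were read from the labels and matched to GENCODE v29 transcripts, since no genome sequence was at hand. Sites outside them have no position. Calls were checked on 20 simulated sets of unchanged groups, with at most 3 genes called over 11 comparisons. Also, 100 genes, some events and some lists were changed by known amounts. Of events changed by 30 points the test found 59 to 84% for groups of 4 libraries and 31 to 42% for groups of 2. Of those changed by 15 points it found at most 2%, so most such shifts went unseen. A log2 shift of 0.4 was found in 10 of 10 lists, with 2 others called. Real duplicates varied unequally and in part together, so real error rates may differ. Exact permutation tests were used for single values per library. Alternatives tried were other size factors, no filter on low counts, replicate number as a block, fits with a comparison's own libraries, hgRNAs taken as replicates, each control hgRNA alone, each library left out, and for splicing other coverage and difference limits. Added after the data were seen were fits without the knockout replicate 1 libraries, without 3 replicate 2 libraries, with the trend in transcript GC content and length removed (known for 96.73% of genes), with events between 5 and 95%, and without introns whose ends had unequal reads.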

Results

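The data were total RNA sequencing of hTERT RPE-1, a telomerase-immortalised human line of retinal pigment epithelium. Cells carried Cas9, Cas12a and hybrid guide RNAs (hgRNAs, a Cas9 guide joined to a Cas12a guide), so that a single transcript cut a gene at 2 sites. There were 34 libraries in 17 hgRNA groups of 2 biological duplicates. Of these groups, 2 carried deletions between genes and served as controls (n = 4 libraries). Deletions inside introns or of exons with a premature stop codon (PTC exons) were made with 2 hgRNAs each in DDX5, DDX17, HDAC7 and, at 2 targets, FNBP4 (n = 4 each). HNRNPD was deleted with 1 hgRNA, and DDX5, DDX17, FNBP4 and HDAC7 were also targeted for knockout with 1 hgRNA each (n = 2 each). Both HDAC7 deletion hgRNAs carried the same Cas9 guide, as did FNBP4 hgRNAs 2 and 3, so agreement between the HDAC7 hgRNAs is not independent of that guide. The genes edited code for RNA helicases (DDX5, DDX17), a formin-binding splicing-associated protein (FNBP4), a class IIa histone deacetylase (HDAC7) and an AU-rich element RNA-binding protein (HNRNPD).

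Reads across splice junctions, counted per gene, were the expression measure, with depths given in megareads. The 4 control libraries held 18.01, 16.2, 17.3 and 17.9. Per library the DDX5 deletions held 17.8, 16.3, 16.4 and 15.9 and the DDX17 deletions 19.2, 12.4, 15.5 and 18.02. In the FNBP4 intron deletions there were 20.1, 16.8, 19.7 and 15.6 and in the FNBP4 PTC exon deletions 15.03, 18.8, 18.01 and 18.5. The HDAC7 deletions held 18.1, 16.3, 16.7 and 15.7 and the HNRNPD deletion 17.4 and 15.1. The knockout libraries held 20.2 and 16.9 (DDX5), 16.6 and 17.7 (DDX17), 15.1 and 18.4 (FNBP4) and 15.9 and 16.3 (HDAC7). After filtering 12081 genes were tested. In simulated sets 100 genes were changed 2-fold. The test found 89 to 94% of them for groups of 4 libraries and 81 to 88% for groups of 2. For a 1.5-fold change these shares were 55 to 70% and 35 to 42%, so a gene not called here may still have moved by that much.

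DDX5 mRNA stood at 552 ± 32.2 depth-scaled counts (CPM, mean ± SD, n = 4) in controls, fell to 150 ± 23.8 (n = 2) in the DDX5 knockout (log2 fold change -1.88, adjusted p = 8.3e-07) and to 406 ± 14.5 (n = 4) in the DDX5 deletion (-0.44, adjusted p = 0.0441). DDX17, its paralogue, rose in both, from 415 ± 15.6 to 633 ± 5.29 CPM in the DDX5 knockout (0.61, adjusted p = 0.000222) and 521 ± 24.9 CPM in the DDX5 deletion (0.33, adjusted p = 0.00438). In its own knockout DDX17 fell to 308 ± 32.1 CPM (-0.44, adjusted p = 0.0133), while the DDX17 deletion left it at 426 ± 17.3 (0.04, adjusted p = 0.866). FNBP4 rose from 39.7 ± 4.60 to 124 ± 23.4 CPM when its PTC exon was deleted (1.63, adjusted p = 1.26e-05) and was not called in the FNBP4 intron deletion (50.2 ± 2.30 CPM, 0.34, adjusted p = 0.481). DDX17 also rose in the FNBP4 PTC exon deletion, to 605 ± 81.3 CPM (0.53, adjusted p = 2.76e-05), and in the HNRNPD deletion, so its rise is not particular to DDX5. HNRNPD rose to 311 ± 65.3 CPM in the FNBP4 PTC exon deletion (0.42, adjusted p = 0.00705), and FNBP4 was not called in the DDX5 deletion (59.4 ± 3.49 CPM, adjusted p = 0.0719), with every library above the controls. HDAC7 stood at 202 ± 29.5 CPM in controls and 171 ± 48.9 in the HDAC7 deletion (-0.27, adjusted p = 0.418); this fall was called only without the GC and length trend, and hgRNA 1 replicate 2 stood apart at 243.5 CPM. HNRNPD went from 230 ± 25.9 to 283 ± 49.9 CPM in its deletion (adjusted p = 0.188).

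The libraries labelled FNBP4 knockout held 33.3 ± 15.6 CPM of FNBP4 (-0.31, adjusted p = 0.535), and those labelled HDAC7 knockout held 179 ± 0.769 CPM of HDAC7 (-0.16, adjusted p = 0.664). Neither target mRNA was called lower, so the labels are used here as names and not as evidence of lost protein. The authors' deposited table gave log2 fold changes of -1.85 for DDX5 in its knockout, -0.56 for DDX17 in its knockout, and 1.61 and 1.27 for FNBP4 with the 2 hgRNAs at the PTC exon. DDX5 in the DDX5 deletion was -0.41 and -0.38 there, each from a single hgRNA, with FDR of 0.24 and 0.337. Gene and event p-values measure spread within biological duplicates of an hgRNA in a single line. List p-values compare genes.

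**Figure D1:**
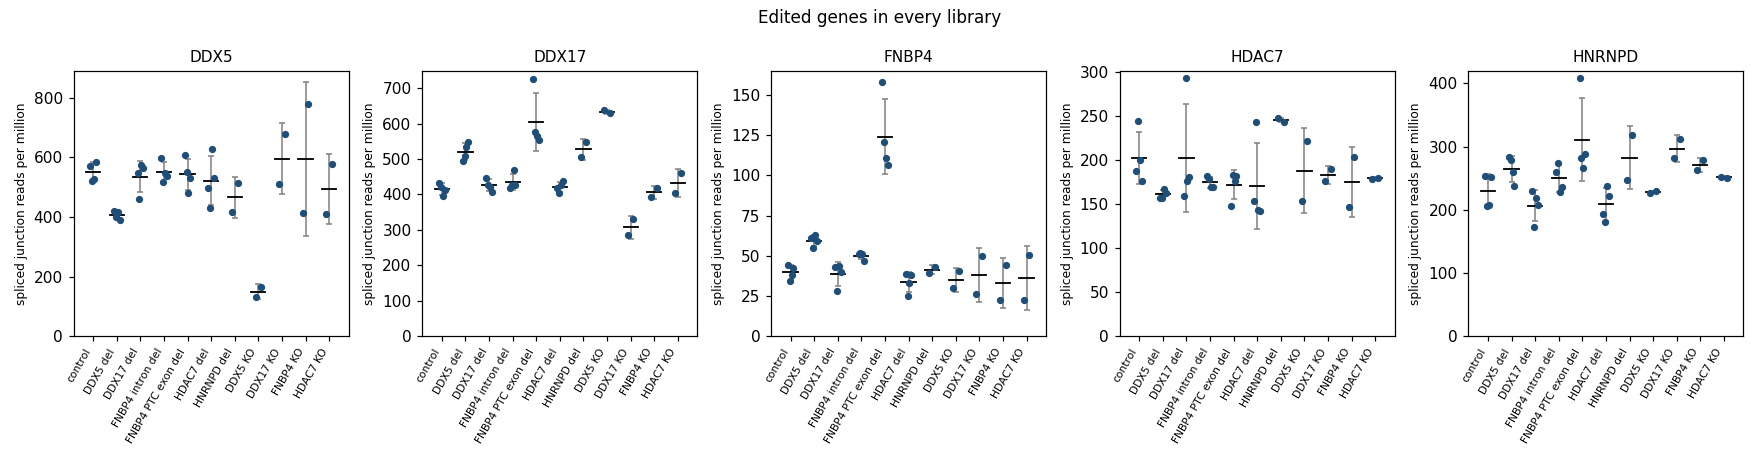
Junction-read CPM (vertical axis) of the 5 edited genes in each hgRNA group (horizontal axis). Points are libraries, lines are means and bars are ± SD.

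**Figure D2:**
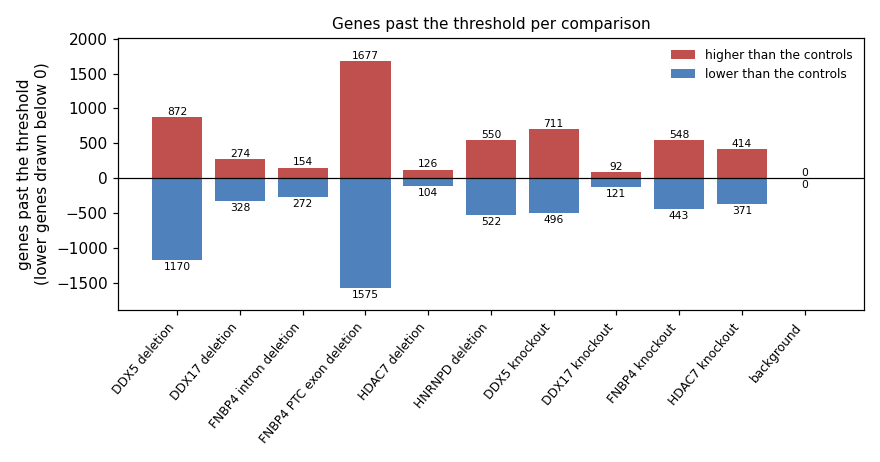
Genes called higher and lower (adjusted p < 0.05) in each comparison with the 4 control libraries. Bars give the number of genes.

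The hgRNAs of the DDX5 deletion target about 450 bases of an intron; 4 libraries were compared with 4 controls. SERPINB2, an inhibitor of plasminogen activators, rose from 18.3 ± 4.89 to 134 ± 47.4 CPM (log2 fold change 2.83, adjusted p = 6.49e-13). The collagen chain COL1A1 fell from 954 ± 354 to 113 ± 49.1 CPM (-3.11, adjusted p = 4.74e-07). The hypoxia-induced carbonic anhydrase CA9 fell from 16.004 ± 6.10 to 0.790 ± 0.367 CPM (-4.31, adjusted p = 7.08e-06). In total 872 genes were higher and 1170 lower, of which 268 and 312 passed in each hgRNA alone. Other large rises were in the titin-binding gene MYPN, the adhesion gene SVEP1, the glucosidase MGAM, the protease ADAMTS1, SERPINB7, the phosphatase PTPRR and SOCS2, with log2 changes of 1.73, 1.67, 1.66, 1.54, 1.43, 1.40 and 1.34. Large falls were in the proteoglycan BGN, the protease PRSS23, the microfibril gene MFAP2, POSTN, IFITM10, the complement protease C1R and the prostacyclin synthase PTGIS, with log2 changes of -2.98, -2.82, -2.58, -2.48, -2.41, -2.40 and -2.26.

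Hypoxia and glycolysis genes fell as a list, with 13 lower and 1 higher of 22 (15 and 1 adjusted over the list alone, camera adjusted p = 1.46e-09). Examples are P4HA1, NDRG1 and P4HA2 (log2 -0.92, -1.16 and -0.69). Among matrix and contractile genes 8 were lower and 2 higher of 22 (10 and 2 adjusted over the list alone, camera adjusted p = 0.000435), including TGFBI at 464 ± 48.3 against 1194 ± 56.3 CPM. Interferon response genes were also lower, 9 of 18 (11 adjusted over the list alone), among them IFI44L, IRF9 and HERC5 with log2 changes of -1.32, -0.48 and -0.44; that list had an adjusted p of 0.000435, and adjusted p = 0.150 with an estimated correlation. Nuclear speckle components were called higher (2 of 24, 1 adjusted over the list alone), as were genes with detained introns, which are spliced late in the nucleus (3 higher and 1 lower of 27, 4 and 1 adjusted over the list alone). SON and RBM39 rose in both lists (0.39 and 0.56). Their adjusted p-values were 0.00157 and 0.0234, and adjusted p = 0.731 and 0.840 with an estimated correlation; the detained-intron call also ended without the GC and length trend.

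Outside called lists the helicases DDX47 and DDX21 rose (0.56 and 0.47), with 3 higher and 1 lower of 28 in their list (adjusted p = 0.0691). Of 30 p53 targets 6 rose and 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.414), FAS and MDM2 up (0.37 and 0.53) and BBC3 down (-0.91). Immediate-early genes split 4 higher and 4 lower of 17 (4 and 5 adjusted over the list alone, adjusted p = 0.626), with DUSP5 (0.92) the largest named rise. Removing libraries moved the 2042 called genes to 1052 without control hgRNA 1 replicate 2, 1090 without control hgRNA 2 replicate 1, 1276 and 1305 without replicates 1 and 2 of deletion hgRNA 1, and 1162 without hgRNA 2 replicate 2. Fitted with its own 8 libraries the comparison gave 3748 genes and against control hgRNA 2 alone 655, while removal of the GC and length trend made 1394 of 2442 calls higher.

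Splicing was tested on 281477 events with at least 20 reads in every library, and 91 events in 85 genes passed adjusted p < 0.05 with a shift of 10 points. Of these, 51 were introns retained more and 1 an intron retained less, beside 18 exons included more, 14 included less and 7 splice sites. Without a size limit 567 introns were retained more and 25 less, and the median of 72468 moved by 0.246 (logit). Exon-intron reads were 2.23 to 2.45% (hgRNA 1), 2.65 to 2.69% (hgRNA 2) and 2.11 to 2.57% (controls). In FKBP11, coding for an endoplasmic reticulum prolyl isomerase, an intron went from 27.6 ± 2.13 to 72.3 ± 7.30% retained (adjusted p = 0.00926), and introns of TMEM44, MIR222HG, ZNF287 and SELENON shifted the same way. An exon of the vesicle fusion gene VTI1B went from 14.2 ± 4.03 to 48.998 ± 1.25% included (adjusted p = 0.000645), and exons of TNS3, ADNP, KPNA6 and WIZ were included more. None of these events lay in the 5 edited genes. Leave-one-out counts ran from 18 to 84, with 23 without control hgRNA 1 replicate 2, 18 without control hgRNA 2 replicate 1, 34 and 54 without replicates 1 and 2 of hgRNA 1, and 49 and 47 without those of hgRNA 2.

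**Figure D3:**
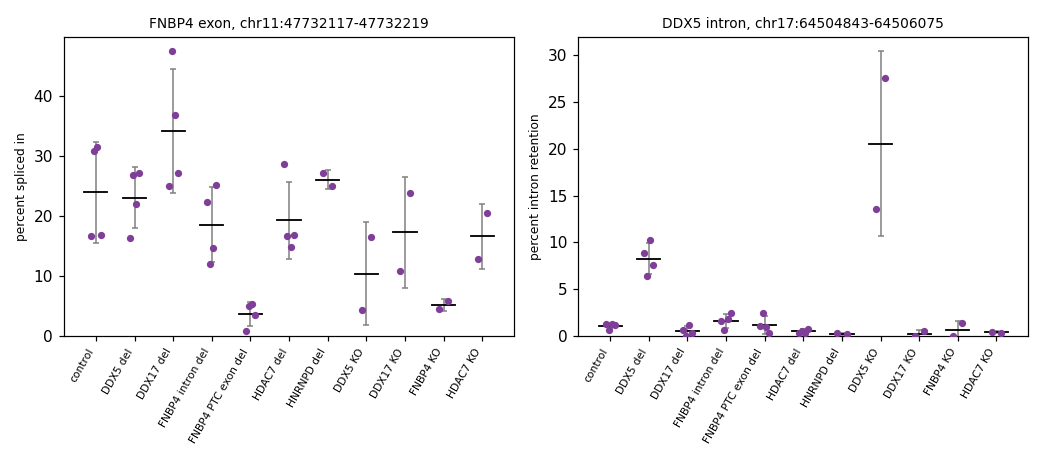
Percent inclusion of the FNBP4 PTC exon and percent retention of the DDX5 intron changed in the DDX5 knockout (vertical axes), by hgRNA group (horizontal axes). Points are libraries, lines are means and bars are ± SD.

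DDX17 mRNA was not called in the DDX17 deletion (4 libraries). SERPINB2 rose to 55.5 ± 9.79 CPM (1.62, adjusted p = 7.09e-08). BGN fell from 31.4 ± 7.998 to 10.6 ± 1.22 CPM (-1.54, adjusted p = 6.77e-07) and smooth-muscle actin ACTA2 from 425 ± 32.5 to 201 ± 21.6 (-1.08, adjusted p = 1.26e-07). The BMP regulator BMPER, SERPINB7, the kinases NEK10 and PRKCH, ADAMTS1 and DAW1 also rose, with log2 changes of 1.38, 1.09, 1.07, 1.05, 1.03 and 1.01. C1R, the chemokine CCL2, ITGA10, the Notch target HES1, PTGIS and SNED1 fell, with log2 changes of -1.35, -1.26, -1.25, -1.22, -1.19 and -1.07. Altogether 274 genes were higher and 328 lower (527 and 445 without the GC and length trend).

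DNA replication genes moved down, 6 of 27 (17 adjusted over the list alone, camera adjusted p = 2.75e-08), among them MCM4, MCM6 and MCM10 (-0.45, -0.34 and -0.39). Mitotic genes did too, 5 of 25 (18 adjusted over the list alone), with UBE2C, CCNB2, CDK1 and FOXM1 at -0.49, -0.55, -0.42 and -0.42; the adjusted p was 6.15e-11, and adjusted p = 0.101 with an estimated correlation. The p53 targets were shifted up with 0 higher and 1 lower past the threshold (2 and 2 adjusted over the list alone), the named member PLK2 going the other way (-0.37). NF-kB and cytokine genes were shifted down, 1 higher and 2 lower of 16 (1 and 4 adjusted over the list alone), with IL1B up and NFKBIA down (0.62 and -0.50). Those adjusted p-values of 0.00487 and 0.0463 became adjusted p = 0.107 and 0.101 with an estimated correlation. The 602 called genes became 291 without control hgRNA 1 replicate 2, 215 without control hgRNA 2 replicate 1, 1271 without hgRNA 1 replicate 1, and 367 and 195 without replicates 1 and 2 of hgRNA 2. With its own 8 libraries alone the count was 31, and against control hgRNA 2 alone 83.

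Of 243476 events tested, 1 exon passed, included less, and limma gave no call at any DDX17 event. The PTC exon named as the target was included at 0.8% in controls, too little for its loss to be seen. That single event became 85 without hgRNA 1 replicate 1, 8 without hgRNA 1 replicate 2, 6 without control hgRNA 2 replicate 2, 5 without hgRNA 2 replicate 2, and 2 without hgRNA 2 replicate 1 or replicate 1 of either control hgRNA.

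Deletions in an FNBP4 intron (4 libraries) moved several of the genes named for DDX17. SERPINB2 rose to 60.1 ± 7.63 CPM (1.74, adjusted p = 1.34e-08), and ACTA2 fell from 425 ± 32.5 to 166 ± 7.96 CPM (-1.36, adjusted p = 5.27e-09). COL1A1 went down from 954 ± 354 to 315 ± 25.1 CPM (-1.54, adjusted p = 0.00576). BMPER, SERPINB7, ADAMTS1, the potassium channel regulator ABCC9, MYPN and DAW1 rose, with log2 changes of 1.30, 1.07, 1.05, 1.04, 1.02 and 1.01. CA9, PRSS23, CCL2, PNRC1, C1R and CRIP2 fell, with log2 changes of -1.79, -1.70, -1.33, -1.32, -1.31 and -1.30. In all 154 genes were higher and 272 lower, 66 of them called in each hgRNA alone.

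Matrix and contractile genes were shifted down, 4 lower and 1 higher of 22 (7 and 2 adjusted over the list alone, adjusted p = 0.000231). NF-kB and cytokine genes followed, 4 lower and 1 higher of 16 (5 and 1 adjusted over the list alone, adjusted p = 0.00260), where IL1B was the riser (0.58). Hypoxia and glycolysis genes had 3 lower and 1 higher of 22 (7 and 1 adjusted over the list alone, adjusted p = 0.000823, and 0.211 with an estimated correlation), and AU-rich element mRNAs, which turn over quickly, had 3 lower of 18 (5 adjusted over the list alone, adjusted p = 0.00788, estimated 0.211), PLAU among them (-0.53). Interferon response genes had 2 lower of 18 (4 adjusted over the list alone, adjusted p = 0.00788, estimated 0.211), IFI44L at -0.89. The integrated stress response list had 1 lower of 19, ASNS at -0.47 (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.0358, estimated 0.211). DEAD and DEAH box helicases were shifted up with 0 members past the threshold of 28 (adjusted p = 0.0156, estimated 0.211). The helicase, stress response and AU-rich calls ended without the 3 replicate 2 libraries that stood apart together.

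The 426 called genes became 160 without control hgRNA 1 replicate 2, 147 without control hgRNA 2 replicate 1, 125 without hgRNA 1 replicate 1, and 203 and 167 without replicates 1 and 2 of hgRNA 2. With its own 8 libraries the count was 1093, against control hgRNA 2 alone 61, and without the GC and length trend 347 higher and 338 lower. No event of 285487 passed in limma (18101 had unadjusted p < 0.05). That 0 became 7 without control hgRNA 2 replicate 2, 6 without replicate 1 of either hgRNA, 5 without control hgRNA 1 replicate 1, and 1 without control hgRNA 2 replicate 1 or hgRNA 2 replicate 2.

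When the FNBP4 PTC exon was deleted FNBP4 itself rose to 124 ± 23.4 CPM, and the synaptotagmin SYT12 rose from 2.16 ± 0.310 to 11.2 ± 1.42 CPM (2.37, adjusted p = 1.56e-08). The growth factor receptor PDGFRA rose from 19.3 ± 1.39 to 63.2 ± 13.2 CPM (1.69, adjusted p = 8.76e-10). SERPINB2 fell from 18.3 ± 4.89 to 1.43 ± 0.594 CPM (-3.71, adjusted p = 7.06e-10), and the cell-cycle inhibitor CDKN1A from 288 ± 60.2 to 83.2 ± 22.5 (-1.81, adjusted p = 2.45e-06). Altogether 1677 genes were higher and 1575 lower, and 535 and 493 passed in each hgRNA alone. The urea transporter SLC14A1, THSD7A, the retinoic acid carrier CRABP2, LXN and OLFML2A rose, with log2 changes of 2.30, 1.46, 1.44, 1.40 and 1.40. TNFRSF11B, the BMP antagonist GREM1, RGMB, SH2D5, complement C3, BMPER and ADAMTS1 fell, with log2 changes of -2.31, -2.19, -2.09, -2.06, -2.01, -1.98 and -1.97.

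Of 30 p53 targets 23 fell and 1 rose (24 and 1 adjusted over the list alone, camera adjusted p = 1.23e-11), with SESN2, DRAM1 and TIGAR at -1.09, -1.23 and -0.75. DNA replication genes fell too, 23 of 27 in either adjustment (camera adjusted p = 1.88e-12), including E2F1, CDC6, CDC45 and FEN1 (-1.41, -0.82, -0.77 and -1.81). Cholesterol synthesis genes had 18 lower of 21 (20 adjusted over the list alone, adjusted p = 5.79e-10), with HMGCS1 and INSIG1 at -0.78 and -0.64. Of the integrated stress response list 12 of 19 were lower (16 lower and 1 higher adjusted over the list alone, adjusted p = 1.65e-07), with the amino acid transporters SLC3A2 and SLC7A5 at -1.08 and -1.21. AU-rich element mRNAs fell, 8 lower and 2 higher of 18 in either adjustment, with CCND1 and GADD45A at -1.34 and -1.41, and snoRNA host genes fell, 5 of 15 (6 adjusted over the list alone), with SNHG15 and SNHG17 at -1.24 and -0.93. Upward lists were hnRNP proteins, 11 higher and 2 lower of 25 (12 and 2 adjusted over the list alone), HNRNPC, HNRNPU and HNRNPUL1 rising (0.41, 0.43 and 0.36) while PTBP1 fell (-0.47), and genes with detained introns, 8 higher of 27 in either adjustment, CLK4 at 0.54. These last 4 lists, at adjusted p 0.000719, 0.0274, 0.0230 and 0.00840, stood at adjusted p = 0.144, 0.292, 0.292 and 0.489 with an estimated correlation, and all but the AU-rich call ended without the GC and length trend.

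Outside called lists SR proteins and their kinases, which steer exon choice, had 3 higher and 1 lower of 19 (2 and 1 adjusted over the list alone, adjusted p = 0.114), with SRSF4 up and SRSF2 down (0.58 and -0.88). Of 18 endoplasmic reticulum chaperones of the unfolded protein response 5 rose (adjusted p = 0.0778). HSPA5, PDIA4 and DNAJC3 rose by 0.37, 0.44 and 0.49. Immediate-early genes had 8 lower and 2 higher of 17 in either adjustment (adjusted p = 0.0557), MYC at -1.17. Of 7 retinal pigment epithelium markers 4 rose and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.164), with the transcription factors OTX2 and MITF up (0.73 and 0.65) and the retinol dehydrogenase RDH5 down (-0.79). The 3252 called genes became 1830 without control hgRNA 1 replicate 2, 1868 without control hgRNA 2 replicate 1, and 1921 and 1947 without replicate 1 of hgRNA 3 and of hgRNA 4. Against control hgRNA 2 alone the count was 1576 and in a fit of its own 8 libraries 2266.

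At FNBP4 itself the PTC exon went from 24.0 ± 8.38 to 3.76 ± 2.02% included (adjusted p = 0.00815), and retention of the next intron downstream (position 47724779 to 47731373), which lies outside the span predicted for hgRNA 3, went from 13.8 ± 2.51 to 2.19 ± 1.18% (adjusted p = 0.00441). The intron that held the exon (position 47731562 to 47732536) went from 27.5 ± 6.54 to 5.47 ± 2.10%, past the threshold when only events of the edited genes were adjusted (adjusted p = 0.0022, 0.0562 over all events). A DDX5 exon (position 64501057 to 64501143) passed in the same way, from 61.7 ± 7.01 to 40.3 ± 7.72% included (0.00455, 0.0806 over all events). In all 36 of 267756 events passed, with 13 exons included more and 10 less, 1 intron retained more and 2 less, and 10 splice sites. Exons of the actin-linked gene PHLDB2 (74.0 ± 3.36 to 54.1 ± 5.07%) and of the autophagy receptor SQSTM1 (65.9 ± 4.54 to 40.6 ± 4.34%) were included less, and an exon of the chromatin remodeller BPTF more (13.2 ± 2.15 to 34.3 ± 5.51%). Those 36 events became 7 without control hgRNA 1 replicate 2, 13 without control hgRNA 2 replicate 1, 12 and 259 without replicates 1 and 2 of hgRNA 3, and 9 and 14 without those of hgRNA 4.

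In the HDAC7 deletion (4 libraries) HDAC7 mRNA was not called, and fewer genes were called than in the other deletions. The lipase inhibitor ANGPTL4 rose from 7.10 ± 1.98 to 16.3 ± 2.95 CPM (1.21, adjusted p = 0.00151), IFFO2 from 41.7 ± 3.41 to 92.2 ± 3.96 CPM (1.15, adjusted p = 4.84e-09), and IGFBP5 from 33.2 ± 4.84 to 74.6 ± 23.1 CPM (1.13, adjusted p = 3.24e-05). CRISPLD2 fell from 17.6 ± 2.96 to 9.13 ± 1.04 CPM (-0.94, adjusted p = 0.000375). MGAM, the natriuretic peptide receptor NPR3, the growth factor NRG1, BMPER and LMCD1 rose, with log2 changes of 0.98, 0.97, 0.91, 0.87 and 0.84. ANGPTL2, the channel KCNK2, the hedgehog mediator GLI3, the origin subunit ORC1, INSIG1, CCNB2 and CDC7 fell, with log2 changes of -0.86, -0.86, -0.85, -0.85, -0.78, -0.72 and -0.70. In total 126 genes were higher and 104 lower, 36 of them called in each hgRNA alone.

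Mitotic genes fell, 14 of 25 (22 adjusted over the list alone, camera adjusted p = 3.46e-23), with UBE2C, CDK1 and KIF20A at -0.51, -0.58 and -0.42. This call and that for DNA replication held without the 3 replicate 2 libraries that stood apart together (control, DDX17 and HDAC7 hgRNA 1). DNA replication genes fell likewise, 6 of 27 (15 adjusted over the list alone, adjusted p = 2.06e-13), MCM4 and RRM1 at -0.57 and -0.37, and so did cholesterol synthesis genes, 4 of 21 (6 adjusted over the list alone, adjusted p = 2.19e-05). Up went matrix and contractile genes, 5 of 22 (10 adjusted over the list alone, adjusted p = 5.58e-09), with ACTA2 and TAGLN at 0.54 and 0.54, the reverse of the fall of ACTA2 in the DDX17 and FNBP4 intron deletions. Hypoxia and glycolysis genes rose, 3 of 22 (10 adjusted over the list alone, adjusted p = 4.04e-08), HK2 and P4HA2 at 0.61 and 0.49, as did p53 targets, 3 of 30 (6 adjusted over the list alone, adjusted p = 3.37e-05), and the integrated stress response list, 2 of 19 (7 adjusted over the list alone, adjusted p = 5.69e-06), VLDLR at 0.63. The unfolded protein response list was shifted up with 0 of 18 past the threshold (3 adjusted over the list alone, adjusted p = 0.000337). Interferon response genes (0 of 18 past, 3 lower adjusted over the list alone) and AU-rich element mRNAs (0 of 18 past, 4 higher adjusted over the list alone) had adjusted p of 0.0132 and 0.0142, and adjusted p = 0.223 and 0.225 with an estimated correlation.

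Leaving libraries out took the 230 genes to 607 without hgRNA 1 replicate 1, 76 without hgRNA 1 replicate 2, 64 and 120 without replicates 1 and 2 of hgRNA 2, 86 without control hgRNA 1 replicate 1, and 90 without either replicate of control hgRNA 2. In a fit of its own 8 libraries the count was 1, and with control hgRNA 1 or 2 alone 109 and 34. No event of 261977 passed in limma (17750 had unadjusted p < 0.05). That 0 became 9 and 3 without replicates 1 and 2 of hgRNA 1, 5 and 1 without those of hgRNA 2, 2 without control hgRNA 2 replicate 2, and 1 without control hgRNA 1 replicate 1.

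HNRNPD was deleted with 1 hgRNA (n = 2), and several genes named for the FNBP4 PTC exon deletion moved the same way. SLC14A1 rose from 6.49 ± 0.938 to 24.0 ± 1.22 CPM (1.89, adjusted p = 3.89e-07) and BGN from 31.4 ± 7.998 to 97.0 ± 14.1 CPM (1.66, adjusted p = 3.89e-07). SERPINB2 fell to 1.79 ± 0.177 CPM (-3.29, adjusted p = 4.5e-07) and C3 from 29.5 ± 4.21 to 8.52 ± 0.796 CPM (-1.78, adjusted p = 0.000367). Further rises were in the laminin LAMA5, OLFML2A, PODNL1, the syndecan SDC3, CRISPLD2 and the repressor HIC1, with log2 changes of 1.77, 1.74, 1.65, 1.56, 1.45 and 1.44. SVEP1, SH2D5, TNFRSF11B, POSTN, the Wnt antagonist DKK1 and CLSTN2 fell, with log2 changes of -1.84, -1.75, -1.61, -1.53, -1.46 and -1.42. The helicase DDX17 rose to 528 ± 29.9 CPM (0.35, adjusted p = 0.0206). Genes called numbered 550 higher and 522 lower (643 and 812 without the GC and length trend).

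DNA replication genes fell, 13 of 27 (19 adjusted over the list alone, adjusted p = 3.36e-13), CCNE2 and MCM6 at -1.10 and -0.51, and so did cholesterol synthesis genes, 10 of 21 (13 adjusted over the list alone, adjusted p = 1.32e-12), HMGCS1, FDFT1 and MSMO1 at -1.09, -0.58 and -0.94. Of the integrated stress response list 7 of 19 were lower (8 lower and 1 higher adjusted over the list alone, adjusted p = 5.76e-07), SLC3A2, SLC7A11 and ASNS at -1.18, -1.17 and -0.76. The p53 targets RRM2B, DRAM1 and FAS fell (-0.81, -1.04 and -0.62) among 7 lower of 30 (9 lower and 1 higher adjusted over the list alone, adjusted p = 5.5e-05). snoRNA host genes were lower in 3 of 15 (4 adjusted over the list alone), GAS5 at -0.83, and mitotic genes in 1 of 25, AURKA at -0.54; their adjusted p of 0.000424 and 0.00404 stood at adjusted p = 0.108 and 0.416 with an estimated correlation. Upward lists were hypoxia and glycolysis (3 of 22, VEGFA at 0.83), hnRNP proteins (1 of 25, HNRNPH2 at 0.86), the unfolded protein response (2 of 18, HSPA5 at 0.36), class IIa HDACs and partners (2 higher and 1 lower of 20, 4 and 1 adjusted over the list alone) and retinal pigment epithelium markers (2 of 7, 4 higher and 1 lower adjusted over the list alone). Hypoxia and glycolysis had an adjusted p of 0.0272 and the other 4 lists 0.0407, and adjusted p = 0.416, 0.361, 0.238, 0.136 and 0.108 with an estimated correlation. AU-rich element mRNAs, bound by HNRNPD, were not called (2 higher and 5 lower of 18, 4 and 6 adjusted over the list alone, adjusted p = 0.612), with ZFP36L2 up and CCND1 down (1.23 and -0.91). The 1072 genes became 323 and 365 without replicates 1 and 2 of the deletion, 667 without control hgRNA 1 replicate 1, 619 without control hgRNA 2 replicate 2, and 416 against control hgRNA 1 alone.

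Of 286953 events 6 passed. Exons of ERICH1, SP140L and the Fanconi gene FANCD2 were included less (FANCD2 at 88.8 ± 7.28% against 100%), an exon of VSIG10 more, an intron of PDXDC2P was retained more and an intron of PACS2 less. None lay in HNRNPD. Leave-one-out counts were 32 and 36 without replicates 1 and 2 of the deletion, 0 without control hgRNA 1 replicate 2, and 3 and 1 without replicates 1 and 2 of control hgRNA 2.

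In the DDX5 knockout (n = 2) DDX5 itself fell. The carrier protein IGFBP3 rose from 214 ± 24.7 to 649 ± 13.3 CPM (1.61, adjusted p = 8.24e-10) and the activin subunit INHBA from 46.4 ± 5.02 to 115 ± 6.63 CPM (1.32, adjusted p = 3.45e-06). The hydrolase MACROD1 fell from 10.3 ± 0.952 to 3.29 ± 0.391 CPM (-1.62, adjusted p = 2.22e-06) and COL14A1 from 11.4 ± 0.873 to 2.54 ± 0.573 (-2.17, adjusted p = 0.000105). BMPER, the hyaluronan synthase HAS2, NRG1, KRT81, endothelin EDN1 and TUBA4A rose, with log2 changes of 1.53, 1.44, 1.41, 1.35, 1.35 and 1.29. ITGA10, SECTM1, the BH3-only gene BMF, SNED1 and CCL2 fell, with log2 changes of -1.83, -1.73, -1.71, -1.66 and -1.59. In all 711 genes were higher and 496 lower.

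Unfolded protein response genes rose, 5 of 18 (8 adjusted over the list alone, camera adjusted p = 3.12e-05), HSPA5, DNAJC3 and CANX at 0.62, 0.45 and 0.57. The other 11 called lists lost the call with an estimated correlation. Of these, 6 rose. Matrix and contractile genes had 7 higher and 2 lower of 22 (8 and 2 adjusted over the list alone), TAGLN up and BGN down (0.85 and -1.04), and p53 targets 5 of 30 (7 adjusted over the list alone), TIGAR at 0.56. Hypoxia and glycolysis genes had 5 higher of 22 (8 and 1 lower adjusted over the list alone), HK2 at 0.78, the respiratory chain 3 of 23, NDUFB10 at 0.65, ribosomal proteins 4 of 45 (5 adjusted over the list alone), RPS14 at 1.07, and keratin genes 1 of 3 (2 adjusted over the list alone), KRT8 at 0.79. In that order the adjusted p-values were 0.00218, 0.00694, 0.0171, 0.0171, 2.47e-05 and 0.0123, and adjusted p = 0.0895, 0.122, 0.405, 0.538, 0.420 and 0.191 with an estimated correlation.

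Falling lists were interferon response genes, 7 of 18 (9 adjusted over the list alone), IFI44L and OAS3 at -1.62 and -1.07, mitosis, 4 of 25 (5 adjusted over the list alone), BUB1 at -0.56, and DNA replication, 5 of 27 (6 adjusted over the list alone), MCM4 at -0.51. NF-kB and cytokine genes had 1 lower of 16 (3 adjusted over the list alone), and cholesterol synthesis genes 4 of 21 (6 lower and 1 higher adjusted over the list alone), HMGCS1 at -0.75. In that order the adjusted p-values were 3.15e-05, 0.000199, 0.00135, 0.0252 and 0.0334, and adjusted p = 0.0895, 0.281, 0.120, 0.0895 and 0.240 with an estimated correlation. The 1207 genes became 154 without knockout replicate 1, 770 without control hgRNA 1 replicate 2 and 652 without control hgRNA 2 replicate 1, and 664 in a fit of its own 6 libraries. Removing the GC and length trend gave 1554 higher and 565 lower and ended the hypoxia and respiratory chain calls. Without knockout replicate 1 libraries the p53, cytokine, hypoxia, respiratory chain and ribosomal calls ended.

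A DDX5 intron (position 64504843 to 64506075) was retained at 20.6 ± 9.86% against 1.14 ± 0.330% in controls (adjusted p = 0.000294). Of 277603 events 9 passed: that intron up, 2 exons included more, 4 less, and 2 splice sites. CASK (14.4 ± 2.89 to 2.54 ± 0.382%) had an exon included less. A DDX17 intron (position 38488116 to 38492055) fell from 15.8 ± 2.74 to 3.83 ± 4.15% only when events of the edited genes were adjusted alone (adjusted p = 0.0131, against 0.221 over all), and reads at its 2 ends were unequal in most libraries; replicate 1 of all 4 knockouts stood at 0.77 to 2.48%. The 9 events became 36 and 72 without knockout replicates 1 and 2, and 2 without control hgRNA 1 replicate 2 or control hgRNA 2 replicate 1.

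Cholesterol synthesis was the clearest loss in the DDX17 knockout (n = 2). HMGCS1 fell from 87.9 ± 9.69 to 32.8 ± 4.31 CPM (-1.42, adjusted p = 9.43e-06) and the reductase TXNRD3 from 31.4 ± 1.84 to 10.8 ± 1.24 CPM (-1.54, adjusted p = 9.43e-06). MACROD1, lower in the DDX5 knockout, rose to 22.5 ± 2.61 CPM (1.13, adjusted p = 6.42e-06), and the kinase MKNK2 rose from 113 ± 10.6 to 208 ± 7.70 (0.89, adjusted p = 0.000575). KRT81, IGFBP5, INHBA, TUBA4A, the sodium-calcium exchanger SLC8A1 and CAMTA1 rose, with log2 changes of 1.21, 1.17, 1.05, 0.90, 0.86 and 0.84. The lipase LIPG, SECTM1, HLA-F, ADAMTS14, C3 and DENND6B fell, with log2 changes of -1.56, -1.54, -1.50, -1.48, -1.43 and -1.43. Called genes were 92 higher and 121 lower.

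Of 21 cholesterol synthesis genes 7 fell (12 adjusted over the list alone, adjusted p = 2.34e-13), INSIG1, MSMO1 and FDFT1 at -1.07, -0.97 and -0.42. DNA replication genes rose, 3 of 27 (7 adjusted over the list alone, adjusted p = 9.57e-07), MCM7 and MCM6 at 0.50 and 0.44, and so did unfolded protein response genes, 2 of 18 (3 adjusted over the list alone, adjusted p = 0.000212). Mitosis (2 of 25, 5 adjusted over the list alone, TPX2 at 0.46), ribosomal proteins (2 of 45, 4 adjusted over the list alone, RPL9 at 0.56), hnRNP proteins (0 of 25) and the integrated stress response (6 of 19 in either adjustment, ASNS and MTHFD2 at 0.63 and 0.77) were shifted up, with adjusted p of 2.2e-05, 5.69e-07, 0.000212 and 0.00540. Matrix and contractile genes (4 higher and 1 lower of 22, 6 and 2 adjusted over the list alone, ACTA2 at 0.70) and hypoxia and glycolysis genes (1 of 22) were up and interferon response genes (1 of 18, 2 adjusted over the list alone, IFI44 at -1.08) down, with adjusted p of 0.00323, 0.000435 and 0.000291. With an estimated correlation, adjusted p = 0.221 for mitosis, 0.343 for ribosomal proteins, 0.205 for hypoxia and 0.0801 for the other 4. The called genes became 25 and 84 without knockout replicates 1 and 2, 141 and 108 without replicates 1 and 2 of control hgRNA 1, and 92 and 125 without those of control hgRNA 2. The ribosomal call ended without knockout replicate 1 libraries. In a fit of its own 6 libraries the count was 17, and without the GC and length trend 301 genes were higher and 221 lower.

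Splicing calls were mostly exons skipped, 17 of 26 events, beside 2 exons included more, 3 introns retained more, 1 less and 3 splice sites (281482 events tested). An exon of MKNK2, whose choice of last exons sets the form of the kinase, went from 46.0 ± 6.09 to 10.98 ± 1.99% (adjusted p = 0.00582). Exons of MORN1 (99.1 ± 1.78 to 58.6 ± 3.66%), MAN2A2 (72.5 ± 8.67 to 35.7 ± 1.67%) and C11orf95 fell as well, while an exon of the kinase MINK1 rose (44.3 ± 2.92 to 79.7 ± 4.71%). Introns of the plexin PLXNA1 (14.5 ± 3.64 to 60.4 ± 1.65%) and of MAN2B2 were retained more. The DDX17 intron at position 38488116 fell to 2.88 ± 2.98% with events of the edited genes adjusted alone (adjusted p = 0.0285, 0.293 over all), while replicate 1 of the other knockouts had 0.9 to 2.48%, and its ends had unequal reads. These 26 events became 51 and 78 without knockout replicates 1 and 2, 13 without control hgRNA 1 replicate 2, and 14 without either replicate of control hgRNA 2; the DDX17 intron call ended without any of the 4 controls.

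The libraries labelled FNBP4 knockout (n = 2) rose in NRG1, from 9.89 ± 1.13 to 30.4 ± 1.59 CPM (1.62, adjusted p = 5.95e-07), and in IFFO2, to 119.2 ± 2.30 CPM (1.52, adjusted p = 6.16e-10). BMF fell from 22.2 ± 6.57 to 3.47 ± 0.0443 CPM (-2.61, adjusted p = 6.17e-05) and INSIG1, a brake on sterol synthesis, from 91.4 ± 12.1 to 27.7 ± 0.554 (-1.71, adjusted p = 3.45e-07). EDN1, the axon guidance gene NAV3, ADAMTS5, HAS3 and IGFBP3 rose, with log2 changes of 1.69, 1.42, 1.35, 1.28 and 1.28. SNED1, ANGPTL2, ITGA10, CCL2, AZIN2, C1R and COL14A1 fell, with log2 changes of -2.11, -2.06, -2.04, -1.93, -1.83, -1.73 and -1.72. In total 548 genes were higher and 443 lower.

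Cholesterol synthesis genes fell, 9 of 21 (10 adjusted over the list alone, adjusted p = 4.79e-09), MSMO1 at -0.91, and unfolded protein response genes rose, 4 of 18 (8 adjusted over the list alone, adjusted p = 1.35e-05), HSPA5 and MANF at 0.68 and 0.51. Interferon response genes were lower, 6 of 18 (9 adjusted over the list alone), IFIH1 at -0.82. Higher were matrix and contractile genes, 5 and 1 lower of 22 (8 and 1 adjusted over the list alone), ACTA2 and THBS1 at 0.90 and 0.74, DEAD and DEAH box helicases, 3 of 28 (8 adjusted over the list alone), DDX21 at 0.61, and ribosomal proteins, 2 of 45. The last 4 had adjusted p of 3.03e-05, 0.00359, 0.000557 and 0.000585, and adjusted p = 0.0668 for 3 of them and 0.544 for ribosomal proteins with an estimated correlation. SR proteins and their kinases split, 2 higher and 2 lower of 19 (3 and 3 adjusted over the list alone, adjusted p = 0.273), with SRSF6 and SRSF7 up and CLK1 and CLK4 down (0.66, 0.56, -1.17 and -0.81). The 991 genes became 210 without replicate 1, 586 without control hgRNA 1 replicate 2, 538 without control hgRNA 2 replicate 1 and 321 in a fit of its own 6 libraries. Removing the GC and length trend gave 1202 higher and 532 lower, and the ribosomal call ended without knockout replicate 1 libraries.

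Of 273170 events 34 passed, with 15 exons included less and 7 more, 7 introns retained less, 0 more, and 5 splice sites. Without replicate 1, which had few exon-intron reads, called introns were 6 more and 4 less, and without replicate 2 they were 6 and 84. An exon of the snoRNA host SNHG1 (86.7 ± 6.46 to 36.3 ± 16.1%) and an exon of RDH5 (82.3 ± 2.05 to 33.3 ± 10.6%) were included less, an exon of FAM228B more (55.1 ± 10.6 to 90.1 ± 2.63%). Introns of MORN1 (14.5 ± 2.20 to 0.435 ± 0.615%) and of the kinase MARK2 (14.7 ± 8.66 to 1.02 ± 1.44%) were retained less. In FNBP4 the PTC exon stood at 5.21 ± 0.940% against 24.0 ± 8.38%, called with events of the edited genes adjusted alone (adjusted p = 0.024, 0.151 over all), as were the introns at positions 47731562 and 47724779 (0.0445 and 0.0106). Replicate 1 libraries of the other 3 knockouts, which share low exon-intron reads, had these introns at 1.82 to 6.12% and 0 to 5.37% as well, and the exon at 4.42 to 12.82%. Those 3 calls became 0 without replicate 1 and 1 without control hgRNA 1 replicate 2 or control hgRNA 2 replicate 1, and the 34 events 77 and 206 without replicates 1 and 2, 20 and 14 without those of control hgRNA 1, and 10 and 22 without those of control hgRNA 2.

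In the libraries labelled HDAC7 knockout (n = 2) the matrix protein POSTN fell from 23.6 ± 1.74 to 2.17 ± 1.64 CPM (-3.62, adjusted p = 1.67e-05) and C3 to 6.79 ± 2.91 CPM (-2.16, adjusted p = 0.000264). NPR3 rose from 6.49 ± 0.573 to 20.5 ± 2.32 CPM (1.65, adjusted p = 2.72e-07) and IFFO2 to 94.1 ± 6.36 (1.17, adjusted p = 1.47e-07); both also rose in the HDAC7 deletion. TUBA4A, HAS2, INHBA, the GDNF receptor GFRA1, NRG1 and the amino acid transporter SLC1A4 rose, with log2 changes of 1.40, 1.22, 1.18, 1.07, 1.05 and 0.99. COL14A1, SNED1, CCL2, GREM1, ANGPTL2 and PNRC1 fell, with log2 changes of -1.95, -1.89, -1.83, -1.82, -1.81 and -1.71. Genes called were 414 higher and 371 lower.

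None of the 8 called lists held with an estimated correlation. Cholesterol synthesis (4 of 21, 6 lower and 1 higher adjusted over the list alone, HMGCS1 and IDI1 at -1.07 and -0.87), interferon response (3 of 18, 8 adjusted over the list alone, IRF9 at -0.83) and NF-kB and cytokine genes (3 of 16, 4 lower and 1 higher adjusted over the list alone, IL1B at -0.89) were lower, with adjusted p of 0.000339, 6.71e-05 and 0.0105. Unfolded protein response genes were higher (2 of 18, 6 adjusted over the list alone, HSPA5 at 0.54, adjusted p = 0.000542); for all 4 adjusted p = 0.0633 with an estimated correlation. Ribosomal proteins (3 of 45, RPS14 at 0.95), DNA replication (3 of 27, 7 higher and 1 lower adjusted over the list alone, CDC6 at 0.49), mitosis (1 of 25, 5 adjusted over the list alone, TPX2 at 0.51) and DEAD and DEAH box helicases (1 of 28, DDX47 at 0.53) were higher. Their adjusted p of 6.79e-06, 0.000539, 0.0145 and 0.00904 stood at adjusted p = 0.433, 0.0807, 0.513 and 0.183 with an estimated correlation. The 785 genes became 60 without replicate 1, 411 without control hgRNA 1 replicate 2, 328 without control hgRNA 2 replicate 1 and 159 in a fit of its own 6 libraries. Removing the GC and length trend gave 1275 higher and 414 lower and ended the mitosis call, and the ribosomal call ended without knockout replicate 1 libraries.

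Of 269503 events 18 passed, 5 exons included more and 1 less, 2 introns retained more and 2 less, and 8 splice sites. Exons of the collagen COL8A1 (33.5 ± 8.06 to 63.4 ± 3.32%) and of the kinase MOK (67.8 ± 5.71 to 87.4 ± 0.912%) were included more, an exon of ZC3HC1 less. An intron of DTD2 was retained more (22.5 ± 5.55 to 54.7 ± 5.11%) and introns of CAV1 (19.3 ± 2.77 to 6.31 ± 0.396%) and PLEKHG2 less. These 18 events became 69 and 94 without replicates 1 and 2, 3 without control hgRNA 1 replicate 2 and 0 without control hgRNA 2 replicate 1.

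Each deletion was compared with the knockout of its gene, which share the 4 controls. DDX5 was 532 genes apart (212 higher and 320 lower in the deletion), DDX17 1072 (521 and 551), the FNBP4 intron 231 (107 and 124), the FNBP4 PTC exon 3712 (1867 and 1845) and HDAC7 727 (360 and 367). Shared calls for DDX5 were 294 genes higher in both and 277 lower in both, against 51.3 and 48.0 under independence, and 18 were opposite against 105. FNBP4 intron deletion and knockout shared 93 higher and 114 lower, with 6 opposite (6.99, 9.97 and 17.985 under independence), DDX17 10 and 17, with 15 opposite (2.09, 3.29 and 5.24), and HDAC7 56 and 22, with 2 opposite (4.32, 3.19 and 7.43). The controls are shared, so independence is not the value expected without a common change. With separate control hgRNAs for the 2 sides, either way round, shared calls were 122 and 96 or 115 and 144 for DDX5, 44 and 49 or 13 and 24 for the FNBP4 intron, 2 and 8 or 1 and 5 for DDX17, 4 and 23 or 5 and 25 for the FNBP4 PTC exon and 13 and 6 or 10 and 5 for HDAC7. For the FNBP4 PTC exon 24 and 56 were shared (76.1 and 57.8 under independence) and 322 were opposite, against 133, the p53 target TIGAR rising in the libraries labelled knockout and falling in the deletion.

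Shared controls alone correlate the fold changes, by about 0.406 in simulated unchanged groups (0.4 for HDAC7). Observed correlations were 0.498 for DDX5, 0.169 for DDX17, 0.541 for the FNBP4 intron, 0.0294 for the FNBP4 PTC exon (-0.0261 without the GC and length trend) and 0.329 for HDAC7. Added variance lowers a correlation and not a covariance, which differed from the simulated by 0.0946, -0.00837, 0.0579, -0.0248 and 0.0197 in that order. With separate control hgRNAs the correlations were 0.362 and 0.429, -0.0109 and 0.0702, 0.36 and 0.404, -0.019 and -0.0686, and 0.277 and 0.0913. Splicing differed at 18, 23, 8, 277 and 5 events in that order. Knockout replicate 1 libraries move these counts, which without them were 132, 310, 57, 2199 and 88 genes.

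The 2 control hgRNAs differed in limma at 0 genes and 0 of 299020 events (157 and 9485 at unadjusted p < 0.05). Between the 2 hgRNAs of a deletion limma also called 0 genes, with 249, 266, 93, 661 and 894 at that p for DDX5, DDX17, the FNBP4 intron, the FNBP4 PTC exon and HDAC7. With 2 libraries a side, 0 calls do not show agreement. Fold changes correlated at 0.427 (HDAC7) to 0.815 (DDX5).

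**Figure D4:**
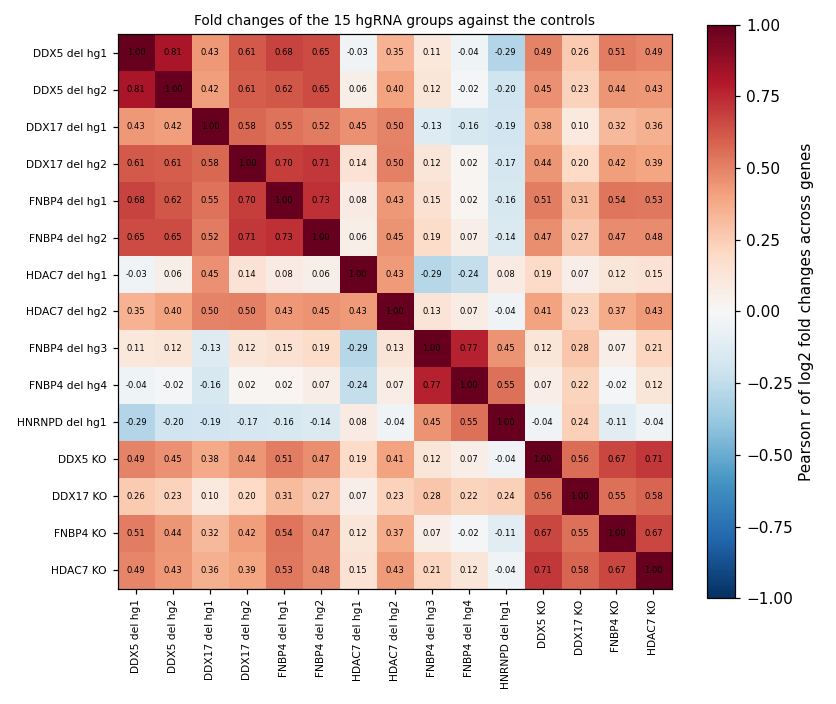
Pearson correlation of log2 fold changes across genes between the 15 edited hgRNA groups, each against the 4 control libraries. Colour gives the correlation.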

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

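The tests of shared changes, of the guide printed for HDAC7 and of genes beyond the edited sites were chosen only after the results were seen; the regrouping tests were planned. For each deletion its 4 libraries and the 4 controls were regrouped in all 35 ways, with a fit of 2 groups to those 8 libraries and no term per hgRNA, so its counts differ from those of the other fits. The real grouping called 3929 (DDX5), 180 (DDX17), 1416 (FNBP4 intron), 2852 (FNBP4 PTC exon) and 46 (HDAC7) genes, and every other grouping 0. For DDX5 splicing it called 174 events, and the highest other grouping 3. Duplicates of an hgRNA were regrouped as if independent, so chance between hgRNAs stays open here. Chance could not be excluded for splicing in the FNBP4 intron deletion, with 1 event against 3 (5 of 35 groupings gave as many). For the DDX17, FNBP4 PTC exon and HDAC7 deletions this fit called 0 events (highest other grouping 1, 3 and 2), so all 35 groupings gave as many by design and the test decides nothing, nor does it test the 36 events of the FNBP4 PTC exon deletion called in the fit of all libraries.

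Groups edited at different genes shared expression changes, with a median correlation of 0.626 over the 6 pairs of knockouts. Shared control libraries alone gave 0.316 to 0.341 in simulated groups, and removal of the GC and length trend left 0.615, so the tables argue against both as the whole cause. Whether the edited gene is the whole cause stays open. The intron and PTC exon deletions of FNBP4 correlated at 0.186 at most, but FNBP4 mRNA was 50.2 CPM in the former and 124 CPM in the latter, so edits of this gene need not act alike. Replicate 1 libraries of different knockouts correlated at 0.602 or more, above the highest value between replicates of a knockout (0.509), so shared handling of these 4 libraries may account for part of the knockout pattern. For the deletions 0 labels name a batch, so shared handling and a shared response to editing cannot be told apart there. Only the library names of FNBP4 hgRNAs 3 and 4 hold the mark enr, whose meaning is not given in the sources used here; the HNRNPD deletion, which goes with them, lacks it.

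The label of the HDAC7 knockout prints the Cas9 guide of the FNBP4 knockout. Its sequence matched only FNBP4 exon 5 among transcripts, so these libraries might have been edited at FNBP4 only. Against that, inclusion of the HDAC7 exon at position 47798108 to 47798219 of chromosome 12 was 94.7 ± 4.50% in them and 100% in each of the other 32 libraries (exact p = 0.00178 over 561 regroupings, the smallest they can give), and the exon at 47798562 to 47798652 was at 96.5 ± 1.93% and 100% (exact p = 0.00178). They were chosen among 214 events of the edited genes after their values were seen, with duplicates regrouped as independent. An edit at HDAC7 and a misprinted guide are thus hypotheses.

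Genes between an edited site and the end of its chromosome arm were lower. Their mean log2 change was -0.0598 after removal of the GC and length trend (permutation p = 1e-05, the smallest 1e+05 resamples can give). P-values here take hgRNAs of a gene as independent and may be too small. The mean without the trend argues against it as the whole cause. The difference of -0.0523 from the rest of the chromosome (permutation p = 3e-05) argues against a whole-chromosome change. By site, groups edited there differed from all other groups by -0.108 for DDX17, -0.0796 for FNBP4, -0.114 for HDAC7 and -0.0602 for DDX5 (exact p = 0.0022, 0.000999, 0.0022 and 0.044; adjusted over the 5 sites 0.00367 for the first 3 and 0.055 for DDX5), and by 0.0482 for HNRNPD (exact p = 0.867). The HDAC7 knockout group was counted at HDAC7 by its label, with a distal median of -0.0539 against -0.137 and -0.119 for the deletion hgRNAs. With the trend kept differences were -0.0941 for DDX17, -0.0857 for FNBP4, -0.107 for HDAC7, -0.134 for DDX5 and -0.0622 for HNRNPD. In that order exact p = 0.0571, 0.000333, 0.0022, 0.0659 and 0.2. Loss of the distal arm in a share of cells after the break may be behind this. No biological explanation was tested.

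Single libraries stood apart from the other 3 of their group in 8 of 42 tests (7 measures in each of 6 sets of 4), where chance picks out about 1 in 20. DDX17 deletion hgRNA 1 replicate 2 had 292.5 CPM of HDAC7 (others 159 to 181) and 3.04% of reads across exon-intron borders (others 2.10 to 2.21). HDAC7 deletion hgRNA 1 replicate 2 had 243.5 CPM of HDAC7 (others 142 to 154) and 2.77% of such reads (others 1.92 to 2.00). FNBP4 PTC exon deletion hgRNA 3 had 726 CPM of DDX17 (others 554 to 576) and 408 CPM of HNRNPD (others 267 to 288) in replicate 1, and 2.47% exon-intron reads (others 1.87 to 1.96) in replicate 2. FNBP4 intron deletion hgRNA 2 replicate 1 had 468 CPM of DDX17 (others 419 to 426).

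Deletion and knockout of the same gene differed at 532 (DDX5), 1072 (DDX17), 231 (FNBP4 intron), 3712 (FNBP4 PTC exon) and 727 (HDAC7) genes. In the authors' deposited table, which covers genes without introns, 22 replication-dependent histone genes were tested. Of these 2 were lower with DDX5 deletion hgRNA 2 and 5 with FNBP4 hgRNA 3, while 1 was higher in the DDX17 knockout and 3 in the libraries labelled HDAC7 knockout. Of 13 mitochondrially encoded genes 1 was higher in the HNRNPD deletion and 0 passed in the other groups.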

How the results depend on the processing

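Alternatives that remove the 4 knockout replicate 1 libraries, 3 replicate 2 libraries that stood apart together, the GC and length trend, events outside 5 to 95% or introns with unequal ends were chosen after seeing the data. Over 785 results and 11378 alternatives, 80.5% kept direction and side of the threshold. Of 9233 values for named genes 84.7% did so and 1401 fell short of the threshold, and of 1063 for named events 56.8% did so and 451 fell short. Other size factors ended 2 of 564 gene calls, no filter on low counts 27, removal of the GC and length trend 26, control hgRNA 1 alone 91, control hgRNA 2 alone 184, and fits with a comparison's own libraries 162. Direction turned in 7 results. Of these 2 were genes in the DDX5 deletion without the GC and length trend, with log2 changes of 0.00997 (PTBP1) and 0.0329. The other 5 were lists without knockout replicate 1 libraries, none called with them: nuclear speckle components (adjusted p = 0.883 in the DDX5 and 0.00151 in the DDX17 knockout), genes with detained introns (0.00209 in the DDX17 knockout and 0.0323 in the libraries labelled HDAC7 knockout) and the respiratory chain (0.481 in the latter). Except where the alternative holds fewer libraries or events, the cause was not tested. DESeq2 and other pseudocounts on normalized values, planned for per-library count or RPKM tables, were not run, nor were counts where an alternative left no events.

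Called genes in own-library fits were 3748 (DDX5 deletion), 31 (DDX17 deletion), 1093 (FNBP4 intron), 2266 (FNBP4 PTC exon), 1 (HDAC7 deletion), 664 (DDX5 knockout), 17 (DDX17 knockout), 321 (labelled FNBP4 knockout) and 159 (labelled HDAC7 knockout). Against control hgRNA 1 alone they were 109 (HDAC7 deletion), 416 (HNRNPD) and 84 (DDX17 knockout). Against control hgRNA 2 alone they were 655 (DDX5 deletion), 83 (DDX17 deletion), 61 (FNBP4 intron), 1576 (FNBP4 PTC exon), 34 (HDAC7 deletion), 452 (DDX5 knockout), 93 (DDX17 knockout), 426 (labelled FNBP4 knockout) and 197 (labelled HDAC7 knockout). Without knockout replicate 1 libraries the 4 knockouts gave 208, 39, 264 and 92 genes, and deletion against knockout 132 (DDX5), 310 (DDX17), 57 (FNBP4 intron), 2199 (FNBP4 PTC exon) and 88 (HDAC7). Without 3 replicate 2 libraries (control, DDX17 and HDAC7 hgRNA 1) the DDX17 deletion gave 366, the HDAC7 deletion 152 and HNRNPD 1757.

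Removing the GC and length trend gave 972 genes (DDX17 deletion), 685 (FNBP4 intron), 452 (HDAC7 deletion), 2119 (DDX5 knockout), 522 (DDX17 knockout), 1734 (labelled FNBP4 knockout) and 1689 (labelled HDAC7 knockout), and 1025, 1616, 502 and 1331 for deletion against knockout of DDX5, DDX17, the FNBP4 intron and HDAC7. It left more genes higher than lower, where fewer had been, in the DDX5 deletion (1394 and 1048), the DDX17 deletion (527 and 445) and the DDX17 knockout (301 and 221), did the opposite in the HNRNPD deletion (643 and 812), and raised it to 50.7% in the FNBP4 intron deletion, 73.3% in the DDX5 knockout, 69.3% in the libraries labelled FNBP4 knockout and 75.5% in those labelled HDAC7 knockout; in deletion against knockout of HDAC7 it fell to 27.8%. Without a filter on low counts the FNBP4 intron deletion had 142 higher and 164 lower. In 9 of the 10 comparisons with controls, all but the DDX5 knockout, the side with more called genes changed in an alternative, so it is not read as a direction. Without knockout replicate 1 libraries the DDX5 knockout had 7 called lists. Without 3 replicate 2 libraries the FNBP4 intron deletion had 4, and calls for detained introns in the DDX5 deletion, hnRNP proteins and retinal pigment epithelium markers in the HNRNPD deletion and mitosis in the libraries labelled HDAC7 knockout were lost, while mitosis and DNA replication held in the DDX17 and HDAC7 deletions. With an estimated correlation called lists numbered 2 (DDX5 deletion), 1 (DDX17 deletion), 2 (FNBP4 intron), 4 (FNBP4 PTC exon), 4 (HNRNPD), 1 (DDX5 knockout), 3 (DDX17 knockout), 2 (labelled FNBP4 knockout) and 0 (labelled HDAC7 knockout), and for the HDAC7 deletion 8 of 10 held.

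Called events against control hgRNA 1 alone were 35 (DDX5 deletion), 0 (DDX17 deletion), 11 (FNBP4 PTC exon), 0 (HNRNPD), 2 (DDX5 knockout), 14 (labelled FNBP4 knockout) and 3 (labelled HDAC7 knockout). Against control hgRNA 2 alone they were 11 (DDX5 deletion), 3 (FNBP4 PTC exon), 0 (HNRNPD), 1 (DDX5 knockout), 9 (DDX17 knockout), 7 (labelled FNBP4 knockout) and 0 (labelled HDAC7 knockout). Events of the edited genes went to 0 in the DDX17 knockout with either control hgRNA, and to 1 and 0 in the libraries labelled FNBP4 knockout. Without knockout replicate 1 libraries events were 32 (DDX5), 77 (FNBP4) and 65 (HDAC7), and at edited genes 1, 0 and 1. Without 3 replicate 2 libraries they were 35 (DDX5 deletion), 9 (DDX17 deletion), 3 (FNBP4 intron), 15 (FNBP4 PTC exon), 7 (HDAC7 deletion), 4 (DDX5 knockout) and 8 (labelled HDAC7 knockout), and at edited genes 1 (DDX5 deletion), 0 (DDX17 knockout) and 1 (labelled FNBP4 knockout). A coverage minimum of 10 gave 140 (DDX5 deletion), 3 (DDX5 knockout) and 1 at edited genes (HNRNPD). A minimum of 40 gave 60 (DDX5 deletion), 0 (DDX17 deletion), 2 (HNRNPD), 14 (DDX5 knockout) and 21 (labelled FNBP4 knockout), and at edited genes 2 (FNBP4 PTC exon) and 1 (labelled FNBP4 knockout). A limit of 15 points gave 20 (FNBP4 PTC exon), 1 (HNRNPD), 5 (DDX5 knockout), 12 (labelled FNBP4 knockout) and 10 (labelled HDAC7 knockout), and at edited genes 1 (DDX5 knockout) and 0 (DDX17 knockout). With hgRNAs as replicates events were 14 (HNRNPD), 15 (DDX5 knockout), 74 (labelled FNBP4 knockout) and 30 (labelled HDAC7 knockout), and 2 at edited genes (DDX5 deletion). Events between 5 and 95% gave 28 (DDX5 deletion), 8 (FNBP4 PTC exon), 1 (HNRNPD), 22 (labelled FNBP4 knockout) and 0 (labelled HDAC7 knockout). Without introns of unequal ends edited genes held 1 (DDX5 knockout) and 0 (DDX17 knockout). With replicate number as a block, the DDX5 knockout had 5 events and the DDX5 deletion 2 at edited genes.

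Leave-one-out counts, where a group left with 1 library was assumed to vary like the others, ran over these ranges. Called genes were 1052 to 2225 (DDX5 deletion), 195 to 1271 (DDX17 deletion), 125 to 583 (FNBP4 intron), 1830 to 4298 (FNBP4 PTC exon), 64 to 607 (HDAC7 deletion), 323 to 940 (HNRNPD), 154 to 1043 (DDX5 knockout), 25 to 141 (DDX17 knockout), 210 to 947 (labelled FNBP4 knockout) and 60 to 738 (labelled HDAC7 knockout). Called events were 18 to 84 (DDX5 deletion), 1 to 85 (DDX17 deletion), 0 to 7 (FNBP4 intron), 7 to 259 (FNBP4 PTC exon), 0 to 9 (HDAC7 deletion), 0 to 36 (HNRNPD), 2 to 72 (DDX5 knockout), 13 to 78 (DDX17 knockout), 10 to 206 (labelled FNBP4 knockout) and 0 to 94 (labelled HDAC7 knockout). At edited genes they were 0 to 1 (DDX5 deletion), 1 to 4 (DDX5 knockout), 0 to 2 (DDX17 knockout), 0 to 4 (labelled FNBP4 knockout) and 0 to 2 (labelled HDAC7 knockout). At this depth at most 2% of simulated 15-point splicing changes were found.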

Other observations

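The comparisons of single events at the edited sites were chosen after their values were seen. A few genes divided the deletions by direction. SERPINB2, ADAMTS1 and BMPER rose in the DDX17 and FNBP4 intron deletions and fell in the FNBP4 PTC exon deletion, and BGN did the reverse. Log2 fold changes between groups edited at different genes correlated at 0.421 to 0.707 among the DDX5, DDX17 and FNBP4 intron deletions and at 0.448 to 0.547 between the FNBP4 PTC exon and HNRNPD deletions, against 0.0211 to 0.186 between the intron and PTC exon deletions of FNBP4. All groups share the 4 controls, and unchanged simulated groups correlated at 0.316 to 0.341, but added variance lowers a correlation: the covariance of FNBP4 hgRNA 3 with the intron hgRNAs was 0.0325 and 0.0377 (simulated 0.0325), and only that of hgRNA 4 was lower (0.00374 and 0.0118). The DDX5 deletion and knockout correlated at 0.455 to 0.492, while the DDX5 knockout correlated at 0.556 to 0.708 with the other knockouts.

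At the edited sites the intron spanning the DDX5 deletion (chromosome 17, position 64500774 to 64502009) was retained at 14.5% in controls, 19.1% and 25.7% with the 2 deletion hgRNAs, 20.8% and 23.7% in the DDX17 deletions, 18.8% and 20.4% in the FNBP4 intron deletions, 20.2% in the HNRNPD deletion and 4.6 to 8.8% in the knockout groups, so the level is not particular to the DDX5 deletion. An exon of HNRNPD (chromosome 4, position 82355304 to 82355401) was included at 94.9 ± 1.36% in the HNRNPD deletion and at 99.8 to 100% elsewhere (exact p = 0.00178, the smallest 561 regroupings can give, duplicates as independent). The DDX5 intron retained in the DDX5 knockout stood at 13.6% and 27.5% in its libraries and at 0 to 10.2% in all others, with group means of 7.6% and 8.9% for the 2 DDX5 deletion hgRNAs.

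The Cas9 guide of DDX17 deletion hgRNA 1 matched no DDX17 transcript and matched PFN1-203. Reads across exon-intron borders were 0.965 to 1.21% of junction reads in the 4 knockout replicate 1 libraries, 1.92 to 2.29% in the knockout replicate 2 libraries and 2.11 to 2.57% in controls.

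Fold changes in the authors' deposited table correlated with those from junction reads at 0.656 to 0.853 over 11382 genes.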
